A study of Mus musculus with 13 samples.

How the data were processed

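The samples were 13 RNA preparations from flow-sorted bone marrow cells of individual mice, 1 mouse per array, in 5 groups. They came from mice carrying the PML-RARA fusion at the murine Ctsg locus (mCG-PR) and from wild-type littermates (WT). Per the labels, 20 ng of total RNA was amplified and hybridised to the Affymetrix Mouse Exon 1.0 ST array, whose probe sets each query part of a gene. The gating of the sorted populations is not given in the sources used here.

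The deposited table held 1 intensity value per probe set and array, for 229581 probe sets and 13 arrays. The submitters' processing notes named RMA and the mm9 build. The RMA version, its settings and any further filter are not given in the sources used here. The deposited intensity values were on a linear scale, from 2.34 to 21748.2, so log2 was taken before any test. No further scaling between arrays was applied. No genome coordinates were used.

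Of the probe sets, 208397 were listed with 1 gene, 3965 with several and 17219 with none; only the first kind was used. The value of a gene on an array was the median log2 value of its probe sets, for genes with at least 3 of them, which left 15123 of 16299 genes. The median number of probe sets per gene was 11. Of these gene symbols, 13158 were current in the RefSeq table, 1910 were updated through a synonym and 55 were not in it. Genes above the 30th percentile of mean log2 value over all arrays, a threshold of log2 6.0, entered the tests, which left 10586 genes.

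The groups were WT KLS (n = 4, 2 mice of 12 weeks and 2 of 13 weeks), mCG-PR KLS of 6 weeks (n = 3), mCG-PR KLS of 13 weeks (n = 2), WT SLAM of 6 weeks (n = 2) and mCG-PR SLAM of 7 weeks (n = 2). The number of arrays limits the precision. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), two-sided, with all 13 arrays in 1 fit of the 5 groups. The comparison of both ages of mCG-PR KLS with WT KLS merged those ages, in a fit of 4 groups. P-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as the threshold. Values after ± are standard errors from limma unless marked SD. The difference of the genotype effect between SLAM and KLS was tested as an interaction contrast.

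Before the data were examined, 23 gene lists were fixed, with 642 entries of which 546 were measured. They covered long-term stem cell, lymphoid-primed progenitor, primary granule, late neutrophil, erythroid, megakaryocyte, B cell, T and NK cell, mast cell and stromal genes. They also covered monocyte, macrophage and dendritic cell genes, myeloid transcription factors and cytokine receptors, and Hox, Meis and Pbx genes. The remaining lists held mitotic, DNA replication, quiescence, retinoic acid pathway, immediate early, interferon response, p53 target, Notch and Wnt pathway, oxidative phosphorylation and sex-linked genes. The 22 lists with at least 5 tested genes were tested with camera at its preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Some genes stood in more than 1 list. Mecom is given here under its older symbol, Evi1. Elane was not analysed here.

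The genes named for each comparison followed a rule fixed before the data were examined. It took the 10 genes with the largest positive and the 10 with the largest negative log2 change among those that passed, with no overlap between the arrays of the groups compared. The overlap condition was dropped for the interaction. Where fewer than 10 genes passed, the 5 genes with the smallest unadjusted p in each direction were given as values. Ctsg, Pml and Rara, and up to 4 members per list, were added. Predicted genes were counted and not named.

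The test was tried on simulated data with the spread of these arrays, with 100 genes changed by 1 and 100 by 2 on the log2 scale among 10586. It recovered 47% of the 1-log2 changes and 100% of the 2-log2 changes for KLS of 13 weeks, with 2 false among 149 calls. For KLS of 6 weeks it recovered 88% and 100%, with 1 false among 189. For both ages together it recovered 94% and 99%, with 1 false among 194. For 13 against 6 weeks it recovered 67% and 100%, with 1 false among 168. For WT SLAM against WT KLS it recovered 70% and 99%, with 87 false among 256. For mCG-PR SLAM against WT SLAM it recovered 58% and 98%, with 217 false among 373. With array weights set by sorted population, the SLAM comparison recovered 10% and 84%, with 28 false among 122. WT SLAM against WT KLS then recovered 42% and 98%, with 28 false among 168. The KLS comparisons recovered more of the 1-log2 changes with these weights: 81% at 13 weeks, 95% at 6 weeks, 99% over both ages and 93% for 13 against 6 weeks. They had 8 to 13 false calls each.

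The alternatives fixed before the data were examined were no filter, a filter at the 50th percentile, the mean of probe sets, quantile normalisation, subtraction of array medians and the replicate number as a block. Others were a fit of the compared groups alone, limma array weights, a trended and robust prior, a change of at least 2-fold, WT KLS replicates 3 and 4 as the only KLS controls, and leaving out each array in turn. Weights by sorted population, a covariate for low Y-linked expression and an exact permutation of list means were added after the data were seen. Among KLS arrays that covariate marked only mCG-PR KLS 6 weeks replicate 3. In the KLS comparisons it therefore equals leaving that array out. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. No other deposited columns were used here.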

Results

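Gene expression was measured on 13 arrays from sorted bone marrow cells of mCG-PR mice, which carry the fusion protein of acute promyelocytic leukaemia, and of WT littermates. KLS cells are the Kit-positive, lineage-negative, Sca1-positive compartment of stem cells and multipotent progenitors. SLAM cells are the compartment enriched for long-term stem cells with receptors of the SLAM family. There were 4 WT KLS arrays, 3 mCG-PR KLS arrays of 6 weeks, 2 mCG-PR KLS arrays of 13 weeks, 2 WT SLAM arrays and 2 mCG-PR SLAM arrays. The WT KLS mice were 12 to 13 weeks old, so the mCG-PR KLS mice of 6 weeks were compared with older controls. The median intensity per array lay between 98.6 and 115.3, and the number of arrays limits the precision of every value.

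The sorted population was the main axis of difference between arrays, with 40.5% of the variance on the first principal component. The second (12.9%) set mainly WT SLAM replicate 2 apart, with a score of 46.78 against -21.81 to 3.01 on the other arrays. The pooled SD of a gene within groups had a median of 0.22 (log2) for KLS and 0.33 for SLAM arrays. Correlations across genes within a group, where genes are not independent replicates, were 0.950 to 0.966 for KLS, 0.828 for WT SLAM and 0.821 for mCG-PR SLAM. The Y-linked genes Eif2s3y and Kdm5d had mean log2 values of 4.28 and 4.23 on the mCG-PR SLAM arrays and 4.53 on mCG-PR KLS 6 weeks replicate 3, against 7.67 to 8.48 on the other arrays. The labels give no sex. Low Y-linked expression coincided with genotype in the SLAM comparison.

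**Figure D1:**
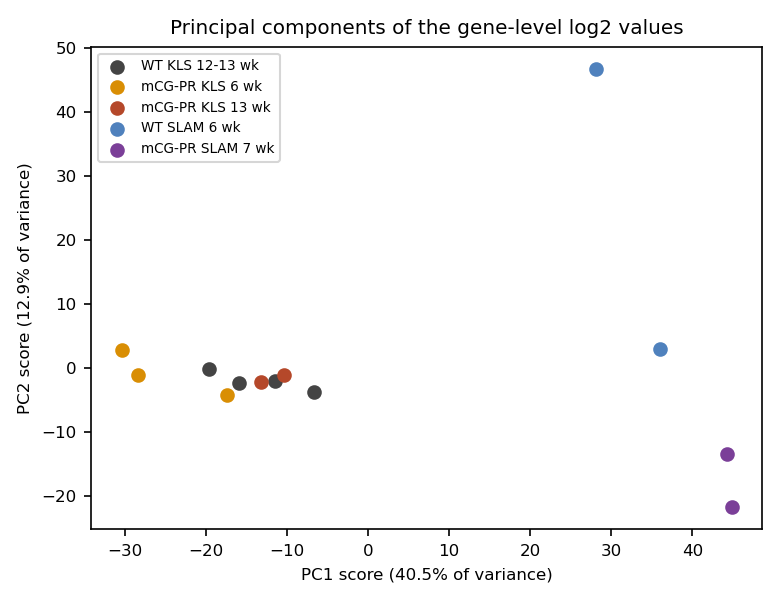
Principal components of the gene-level log2 values, where each point is an array and the axes give the first component (40.5% of variance) and the second (12.9%). KLS and SLAM arrays lie apart along the first component, and WT SLAM replicate 2 along the second. Points are coloured by group.

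The first question was how KLS cells of mCG-PR mice differed from those of WT mice, with both ages pooled (n = 5 against n = 4). Of the 5 mCG-PR mice, 3 were 6 weeks old, while all 4 WT mice were 12 to 13 weeks old. Age is therefore partly mixed with genotype in this comparison. Long-term stem cell genes were lower, and lymphoid-primed progenitor genes and mitotic genes higher, in the mCG-PR cells. Of 26 stem cell genes, 19 had a negative and 7 a positive change, with a median log2 change of -0.13 (camera adjusted p = 3.78e-06, and adjusted p = 0.00646 with an estimated correlation). Examples are Hlf (-0.71 ± 0.24), Meis1 (-0.51 ± 0.18) and Evi1 (-0.66 ± 0.23), transcription factors of stem cell maintenance. Of 17 lymphoid-primed genes, 15 had a positive change, with a median of 0.39 (adjusted p = 1.54e-05, and adjusted p = 0.129 with an estimated correlation). They include Il7r, the interleukin receptor of early lymphoid cells (1.37 ± 0.26), Ly86 (1.05 ± 0.26), the B cell adaptor Blnk (0.63 ± 0.17) and the cytokine receptor gene Flt3 (0.38 ± 0.14). All 29 mitotic genes had a positive change as deposited, with a median of 0.61 (adjusted p = 4.54e-13, and adjusted p = 0.230 with an estimated correlation). Among them are the spindle checkpoint gene Bub1b (0.85 ± 0.20), the transcription factor gene Foxm1 (0.84 ± 0.26) and the kinesin gene Cenpe (0.76 ± 0.25). All genes together shifted by a median of 0.09; relative to that shift the medians were -0.21 for stem cell, 0.30 for lymphoid-primed and 0.52 for mitotic genes. Adjusted over the list alone, 0 stem cell, 3 lymphoid-primed and 11 mitotic genes passed, against 0 in each list over all genes.

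Per array, the mean of the stem cell list was 7.43 ± 0.04 (SD, n = 5) in mCG-PR and 7.60 ± 0.07 (SD, n = 4) in WT KLS (exact permutation p = 0.00794, adjusted 0.0349). The lymphoid-primed mean was 9.06 ± 0.17 against 8.61 ± 0.14 (SD; exact permutation p = 0.00794, adjusted 0.0349), and the mitotic mean 8.08 ± 0.20 against 7.52 ± 0.39 (SD; exact permutation p = 0.0318, adjusted 0.0776). The two-sided test over 126 splits can give no p below 0.00794. This test was chosen after the data were seen. Over 22 lists, a list at that floor cannot pass unless others come near it too. As deposited 8 of 22 lists passed, and 0 after array medians were subtracted, where the adjusted p of each of these 3 lists was 0.146. Their unadjusted exact permutation p was then 0.00794 for stem cell, the smallest possible, 0.0238 for lymphoid-primed and 0.0318 for mitotic genes. After that subtraction the difference was -0.25 for stem cell, 0.36 for lymphoid-primed and 0.48 for mitotic genes, against -0.16, 0.45 and 0.57 as deposited. Of the 8, 5 are among the 11 lists that camera called: stem cell, lymphoid-primed, myeloid factor (adjusted 0.0437), monocyte and dendritic (0.0437) and Notch and Wnt genes (0.0349). The other 3, which camera did not call, were mast cell and basophil (7.56 against 7.16, adjusted 0.0349), stromal and endothelial (6.66 against 6.54, adjusted 0.0349) and interferon response genes (7.51 against 7.38, adjusted 0.0437). Late neutrophil (adjusted 0.200), DNA replication (0.102), T and NK (0.102), erythroid (0.664) and Hox genes (0.417) did not pass it. Against WT KLS replicates 3 and 4 alone, the median change of the mitotic list was 0.30 and that of the stem cell list -0.07.

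**Figure D2:**
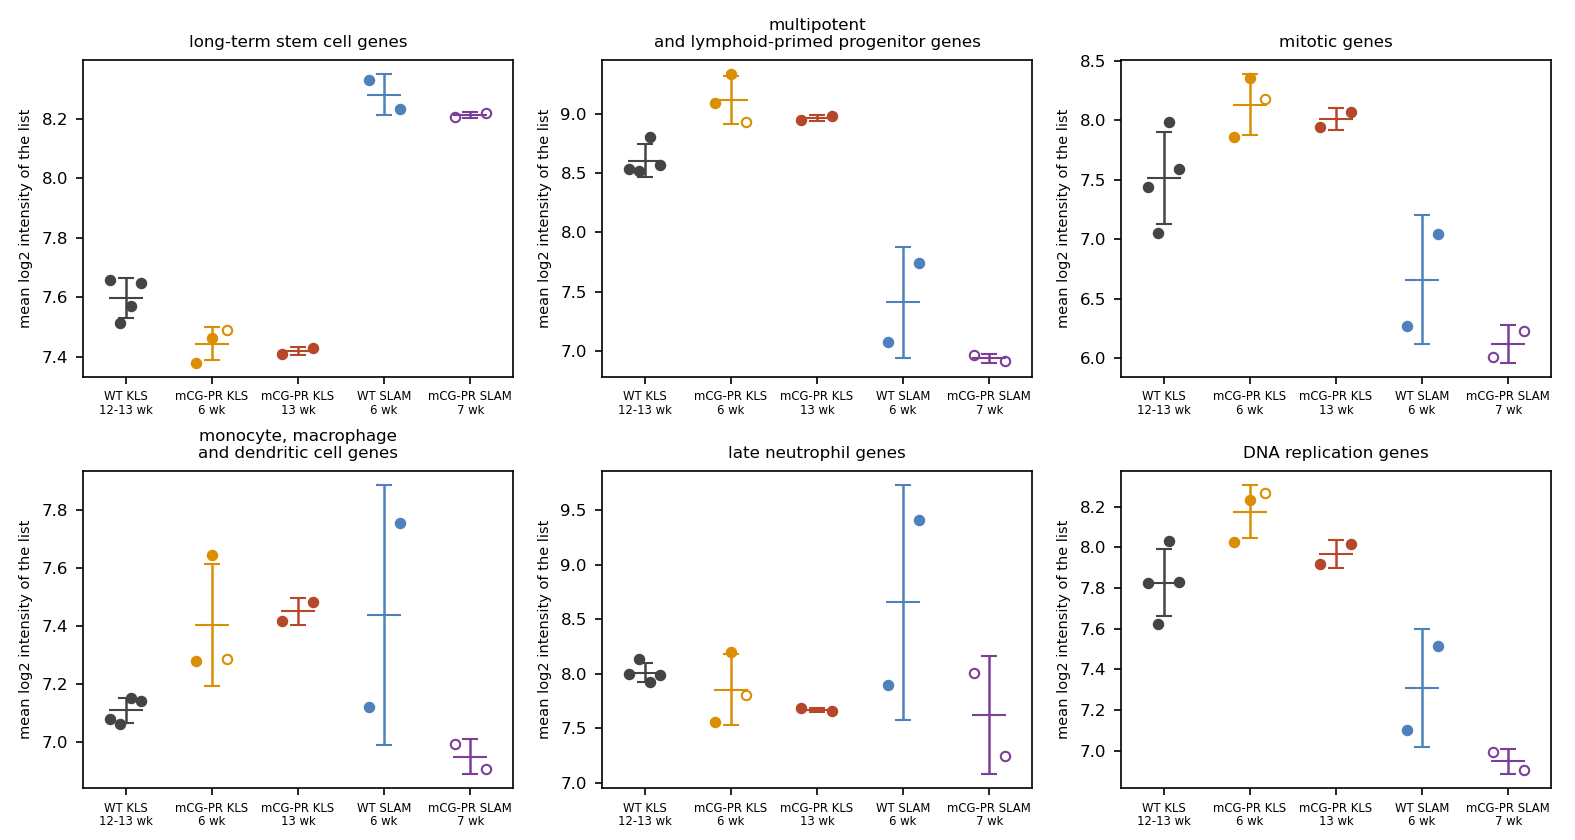
Mean log2 value of 6 gene lists on each array, by group; points are arrays, open points have low Y-linked expression, horizontal bars are group means and error bars SD. The stem cell list averages 7.43 in mCG-PR KLS and 7.60 in WT KLS, and the lymphoid-primed list 9.06 and 8.61.

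Other blood lineage lists also shifted between mCG-PR and WT KLS cells over both ages. Late neutrophil genes were lower, with a median log2 change of -0.15 over 20 genes (adjusted p = 4.91e-04, and adjusted p = 0.390 with an estimated correlation). Their leading member was S100a8, a calcium-binding protein of neutrophils (-1.29 ± 0.36). Without mCG-PR KLS 6 weeks replicate 2 the neutrophil median was -0.25. DNA replication genes were higher, with a median of 0.28 over 31 genes (adjusted p = 3.65e-04, and adjusted p = 0.347 with an estimated correlation). They include Mcm10 (0.48) and the helicase subunit gene Mcm6 (0.61). Relative to the shift of all genes the medians were -0.24 for late neutrophil and 0.19 for DNA replication genes. Against WT KLS replicates 3 and 4 alone the DNA replication median was 0.15 (adjusted p = 0.126). Adjusted over the list alone, 0 genes passed in either list, as over all genes.

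By camera 6 more lists passed, with adjusted p from 0.0194 to 0.0222. Myeloid transcription factors and cytokine receptors were higher (median 0.12, adjusted p = 0.0208, and adjusted p = 0.306 with an estimated correlation), with Klf4 (0.68), the dendritic and monocyte factor gene Irf8 (1.22 ± 0.27), Csf1r (0.77) and Zeb2 (0.61) leading. Monocyte, macrophage and dendritic cell genes were higher (median 0.26, adjusted p = 0.0208, and adjusted p = 0.375 with an estimated correlation). T and NK cell genes were higher (median 0.18, adjusted p = 0.0222, and adjusted p = 0.342 with an estimated correlation), led by Tcf7 (0.85) and Klrd1 (2.30-fold). Notch and Wnt pathway genes were higher (median 0.17, adjusted p = 0.0208, and adjusted p = 0.129 with an estimated correlation), led by Tcf7, Fzd7 (0.64) and Myc (0.48). Erythroid genes were lower (median -0.08, adjusted p = 0.0194, and adjusted p = 0.398 with an estimated correlation), among them Car2 (-0.70). Hox, Meis and Pbx genes were lower (median -0.07, adjusted p = 0.0194, and adjusted p = 0.129 with an estimated correlation). Relative to the shift of all genes these medians were 0.03 for myeloid factor, 0.17 for monocyte and dendritic, 0.10 for T and NK, 0.09 for Notch and Wnt, -0.16 for erythroid and -0.16 for Hox genes. Adjusted over the list alone, 4 myeloid factor, 5 monocyte and dendritic, 2 T and NK, 2 Notch and Wnt and 1 erythroid gene passed, against 0 over all genes. Of 100 splits of the 9 arrays, 5 gave as many passing lists as the real split (11). Each of these 6 calls was lost without certain single arrays. Without WT KLS replicate 1 the adjusted p was 0.287 for T and NK, 0.116 for monocyte and dendritic and 0.0739 for Hox genes, whose median was then 0.02. Without WT KLS replicate 3 it was 0.161 for myeloid factor, 0.354 for erythroid (median 0.06), 0.0549 for monocyte and dendritic and 0.0549 for Notch and Wnt genes. Without mCG-PR KLS 6 weeks replicate 2 it was 0.0997 for myeloid factor, 0.0997 for erythroid and 0.106 for Hox genes. Without mCG-PR KLS 13 weeks replicate 1 it was 0.0757 for T and NK and 0.0816 for Notch and Wnt genes, and without replicate 2 of that group 0.0759 for monocyte and dendritic genes. Medians also moved without single arrays. Without WT KLS replicate 1 they were 0.11 for T and NK and 0.17 for monocyte and dendritic genes, and without WT KLS replicate 4 the latter was 0.40. For erythroid genes the median was -0.15 without WT KLS replicate 2, -0.13 without WT KLS replicate 4 or mCG-PR KLS 13 weeks replicate 1, -0.04 without mCG-PR KLS 6 weeks replicate 1 and -0.03 without replicate 2 of that group. For Hox genes it was -0.03 without WT KLS replicate 2, -0.04 and -0.05 without mCG-PR KLS 13 weeks replicates 1 and 2, and -0.0082 without mCG-PR KLS 6 weeks replicate 3. Without the filter the adjusted p was 0.0841 for erythroid (median -0.0012), 0.225 for T and NK, 0.101 for monocyte and dendritic (median 0.13), 0.0505 for Hox (median -0.04) and 0.0747 for Notch and Wnt genes. Against WT KLS replicates 3 and 4 alone it was 0.275 for T and NK (median 0.06), 0.111 for monocyte and dendritic (0.14) and 0.106 for Hox genes (-0.02), and with the replicate number as a block it was 0.0728 for T and NK genes.

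No single gene passed over both ages: limma called 0 genes, with 760 at an unadjusted p under 0.05, where 529 of 10586 would be expected by chance. The smallest p belonged to Siglech, a receptor of plasmacytoid dendritic cells (1.36 ± 0.21, 2.56-fold, adjusted p = 0.0944), higher in all 5 mCG-PR arrays than in any of the 4 WT arrays. Next came Fkbp5, a glucocorticoid-responsive co-chaperone (1.16 ± 0.20), the lymphoid transcription factor gene Tcf7 (0.85 ± 0.15), Kmo, an enzyme of tryptophan breakdown (1.12 ± 0.21), and Il7r (adjusted p = 0.159). The leading lower genes were Casp12 (-1.31 ± 0.25), Cyp7b1 (-0.69), Cirbp (-0.65), Prkaa2 (-0.85) and Ranbp17 (-0.65), none of which passed. Without WT KLS replicate 3 the count was 6, and without WT KLS replicate 1 it was 1. The error matters too: the count was 9 with the compared groups alone, 29 with limma array weights and 12 with weights by sorted population.

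At 6 weeks, the KLS cells of mCG-PR mice (n = 3) had 3.06-fold more Siglech signal than WT KLS cells (n = 4). The WT mice were 12 to 13 weeks old, so age and genotype cannot be separated in this comparison. The mean log2 value of Siglech was 7.82 ± 0.25 (SD) against 6.21 ± 0.25 (SD), a change of 1.61 ± 0.19 (limma adjusted p = 0.0118), higher in all 3 arrays. It was the only gene limma called of 10586, beside 704 at an unadjusted p under 0.05. The count was 2 with the compared groups alone and 4 with limma array weights. It was 12 with weights by sorted population, a setting chosen after the data were seen. All genes together shifted by a median of 0.11, and relative to that shift Siglech rose by 1.499. The next genes did not pass: Kmo (1.18 relative to the shift), Il7r (1.42) and, lower, the apoptosis-family gene Casp12 (-1.50) and the retinaldehyde dehydrogenase gene Aldh1a1 (-1.02). The Siglech call was lost with the mean of probe sets (adjusted p = 0.130), with the replicate number as a block (adjusted p = 0.0856) and against WT KLS replicates 3 and 4 alone (adjusted p = 0.742). It was also lost without WT KLS replicate 1, 2 or 4 (adjusted p = 0.0767, 0.0742 and 0.0850). Leaving out mCG-PR KLS 6 weeks replicate 1 or 3 lost it as well (adjusted p = 0.0957 and 0.150). Replicate 3 of that group had low Y-linked expression. A covariate for low Y-linked expression marked only that array among the KLS arrays, so it gave the same fit as leaving it out. Without WT KLS replicate 3 there were 3 calls.

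By lists, the KLS cells of 6 weeks showed lower stem cell genes, with a median of -0.22 relative to the shift of all genes (adjusted p = 7.00e-07, and adjusted p = 0.00673 with an estimated correlation). Mitotic genes were higher by 0.51 relative to it (adjusted p = 6.38e-11, and adjusted p = 0.329 with an estimated correlation), lymphoid-primed genes by 0.31 (adjusted p = 1.99e-05, and adjusted p = 0.161 with an estimated correlation) and DNA replication genes by 0.22 (adjusted p = 1.99e-05, and adjusted p = 0.329 with an estimated correlation). Myeloid transcription factors and cytokine receptors were higher by 0.09 (adjusted p = 0.00930, and adjusted p = 0.315 with an estimated correlation). Late neutrophil genes had a relative median of -0.26 (adjusted p = 0.00206, and adjusted p = 0.470 with an estimated correlation). Erythroid genes had a relative median of -0.25 (adjusted p = 8.28e-04, and adjusted p = 0.374 with an estimated correlation) and Hox, Meis and Pbx genes of -0.16 (adjusted p = 0.00206, and adjusted p = 0.107 with an estimated correlation). Adjusted over the list alone, 3 lymphoid-primed and 4 myeloid factor genes passed and 0 in the other 6 lists, against 0 over all genes. Of the 35 splits of the 7 arrays, 8 gave as many passing lists as the real split (8). Without mCG-PR KLS 6 weeks replicate 1 the neutrophil call was lost (adjusted p = 0.0705), and without WT KLS replicate 3 the erythroid (0.0580) and myeloid factor (0.0834) calls were. Without mCG-PR KLS 6 weeks replicate 2 the adjusted p was 0.138 for myeloid factor and 0.0692 for Hox genes. Unshifted, the neutrophil median was -0.14, with -0.0086 without mCG-PR KLS 6 weeks replicate 1 and -0.29 without replicate 2, and the myeloid factor median 0.205, with 0.32 and 0.13 without the same arrays. The erythroid median was -0.13, with -0.06 without mCG-PR KLS 6 weeks replicate 2, and -0.21 and -0.05 without WT KLS replicates 2 and 3. The Hox median was -0.05, with -0.02, -0.08 and -0.09 without WT KLS replicates 1, 3 and 4. Against WT KLS replicates 3 and 4 alone the neutrophil call was lost (adjusted p = 0.0584), and the unshifted mitotic median was 0.38 instead of 0.62.

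**Figure D3:**
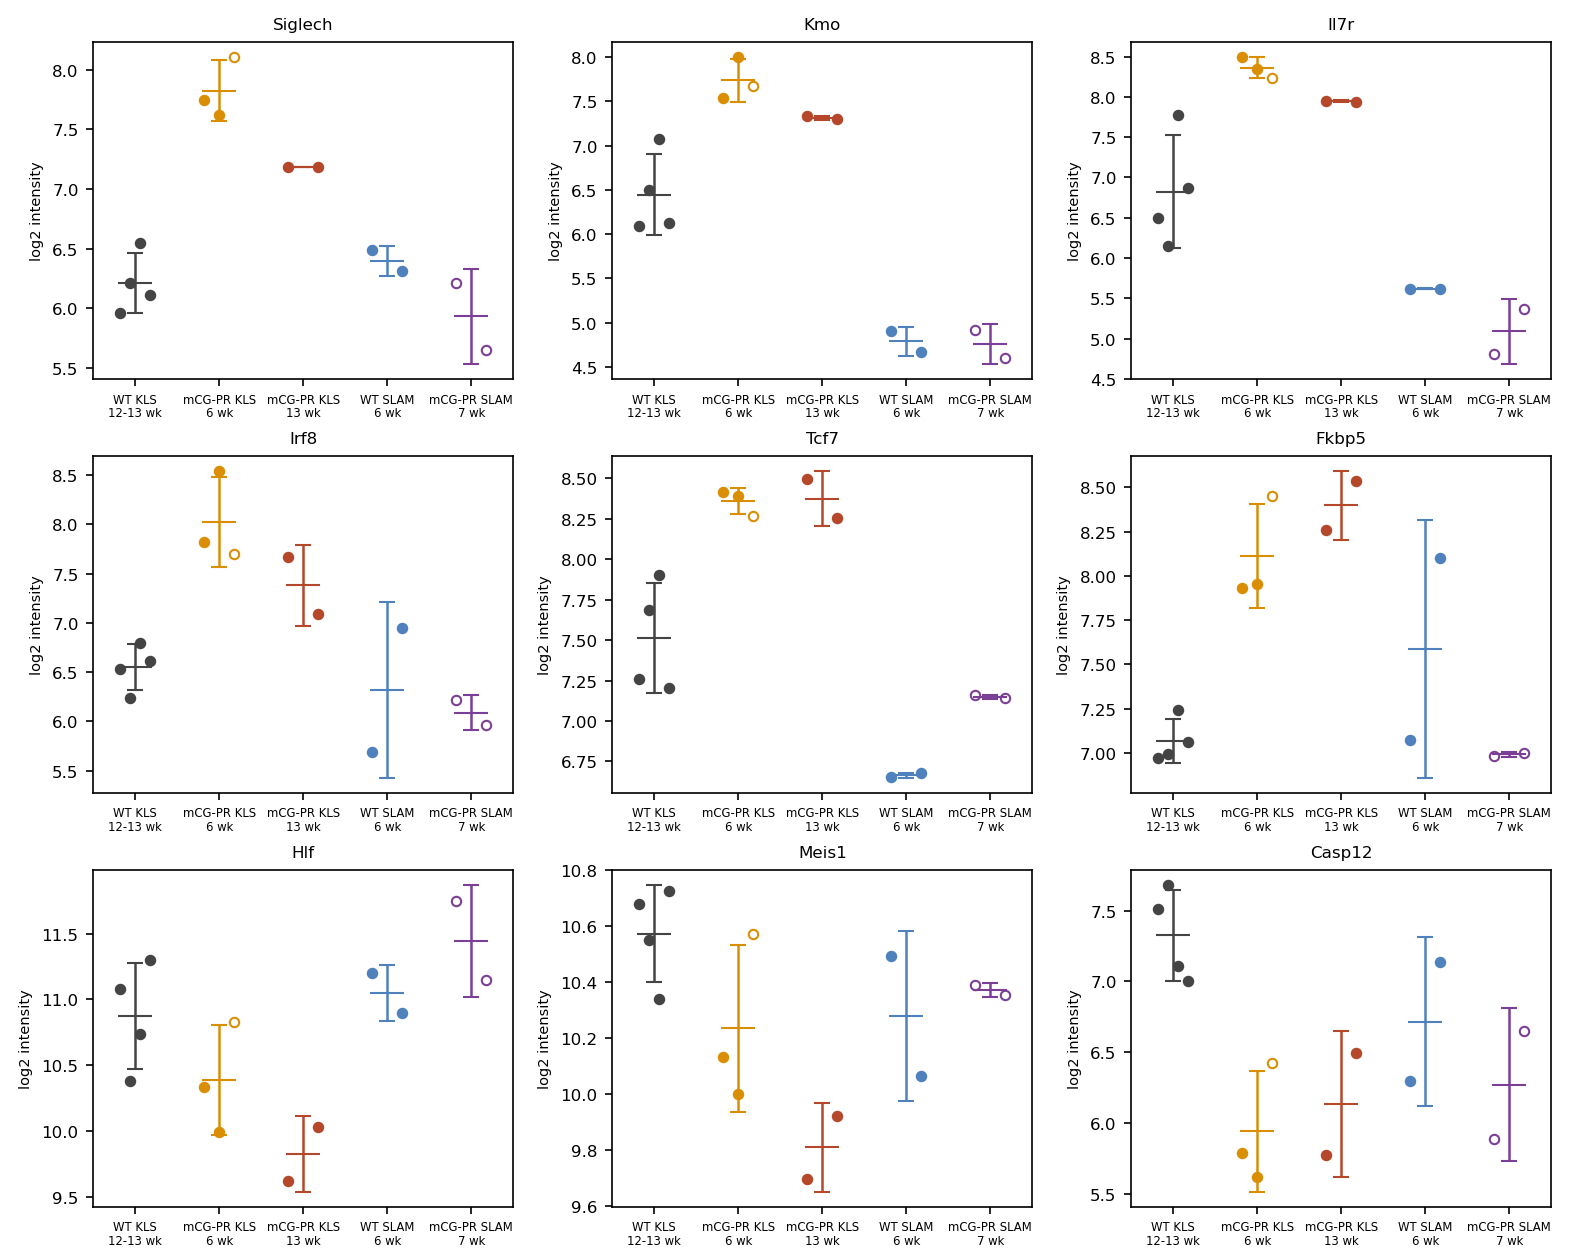
Log2 values of 9 genes on the KLS and SLAM arrays by group; points are arrays, open points have low Y-linked expression, horizontal bars are group means and error bars SD. Siglech averages 6.21 in WT KLS, 7.82 in mCG-PR KLS of 6 weeks and 7.19 in those of 13 weeks.

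At 13 weeks, the age of 2 of the 4 controls, mCG-PR KLS cells (n = 2) were compared with the same WT arrays. They had higher mitotic genes, with an unshifted median of 0.51 (adjusted p = 7.92e-07, and adjusted p = 0.559 with an estimated correlation). Lymphoid-primed genes were higher by 0.34 (adjusted p = 0.0101, and adjusted p = 0.460 with an estimated correlation) and monocyte, macrophage and dendritic cell genes by 0.44 (adjusted p = 0.00662, and adjusted p = 0.460 with an estimated correlation). T and NK cell genes were higher by 0.26 (adjusted p = 0.0196, and adjusted p = 0.460 with an estimated correlation) and Notch and Wnt pathway genes by 0.30 (adjusted p = 0.00662, and adjusted p = 0.104 with an estimated correlation). Stem cell genes were lower, with a median of -0.12 (adjusted p = 0.0106, and adjusted p = 0.104 with an estimated correlation), with Hlf at -1.05, Evi1 at -0.91, Meis1 at -0.76 and Abcg2 at -0.73. Late neutrophil genes were lower, with a median of -0.22 (adjusted p = 0.0146, and adjusted p = 0.575 with an estimated correlation). These medians are unshifted, and all genes together shifted by a median of 0.05. Relative to that shift they were 0.46 for mitotic, 0.29 for lymphoid-primed, 0.39 for monocyte and dendritic and 0.21 for T and NK genes. They were 0.24 for Notch and Wnt, -0.17 for stem cell and -0.27 for late neutrophil genes. Adjusted over the list alone, 3 monocyte and dendritic, 1 T and NK and 1 Notch and Wnt gene rose and 2 stem cell genes fell, against 0 over all genes. Limma called 0 genes, with 782 at an unadjusted p under 0.05. The count was 12 with the compared groups alone, 12 with limma array weights and 0 with weights by sorted population. The leading values were Fkbp5 (1.33 ± 0.25, 2.52-fold, adjusted p = 0.547), Klf4 (0.80 ± 0.17) and Siglech (0.98 ± 0.22), and, lower, the vesicle transport gene Rab11a (-1.11) and Gnpnat1 (-1.03). The neutrophil call was lost without WT KLS replicate 2 (adjusted p = 0.0737) or mCG-PR KLS 13 weeks replicate 2 (0.101), and the T and NK call without WT KLS replicate 1 (0.186) or mCG-PR KLS 13 weeks replicate 1 (0.0864). Without the latter array the stem cell median was -0.19 and the Notch and Wnt median 0.18; against WT KLS replicates 3 and 4 alone the mitotic median was 0.26, and the neutrophil (adjusted p = 0.0912) and T and NK calls (0.130) were lost. Without the filter the T and NK (adjusted p = 0.238) and the monocyte and dendritic calls (0.124, median 0.23) were lost.

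Within mCG-PR KLS cells, 13 weeks (n = 2) and 6 weeks (n = 3) did not differ for any gene or list that passed. Limma called 0 genes, with 669 at an unadjusted p under 0.05, and 0 of 22 lists passed. The leading values were Tefm, a mitochondrial transcription elongation factor (-1.36 ± 0.22, adjusted p = 0.308), Rab11a (-1.11) and Senp5 (-1.11), and, higher at 13 weeks, Aldh1a1 (1.09 ± 0.21, adjusted p = 0.683) and Tac4 (1.12).

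The next question was how SLAM cells of mCG-PR mice differed from those of WT mice (n = 2 against n = 2). Rras2, a Ras-family GTPase, rose in mCG-PR SLAM cells (log2 change 3.08 ± 0.31, adjusted p = 5.38e-04). The homeobox gene Hoxa6 rose 4.49-fold (2.17 ± 0.31, adjusted p = 0.00702), and Parp14, a member of the interferon response list, rose by 1.83 ± 0.26 (adjusted p = 0.00684). Ifi27, of the same list, fell (-1.10, limma adjusted p = 0.0363), and the list, with a median of 0.12, did not pass. Fkbp7, which encodes a chaperone of the endoplasmic reticulum (-3.68 ± 0.34, adjusted p = 5.22e-04), and Ogfrl1 (-2.64 ± 0.27, adjusted p = 5.38e-04) fell. The dimmer group mean of these genes, 5.43 for Rras2, 4.79 for Fkbp7 and 5.11 for Ogfrl1, lay under the filter threshold of log2 6.0, as did that of 9 of the 20 genes named by rule. Other named genes that rose were Mras, Zbtb8os, Eri2, Mid1ip1, Gstm7, Cbx8 and Tmem218, by 1.79 to 2.34. Other named genes that fell were Ngp, Coq10b, Tspan8, S100a1, Ska2, Ltf and Bet1, with changes from -3.06 to -2.42. The Y-linked Eif2s3y had a change of -5.10 ± 1.07 (adjusted p = 0.0274); both mCG-PR SLAM arrays had low Y-linked expression. With the mean of probe sets the change of Hoxa6 was 1.27, and Coq10b (adjusted p = 0.0679), Mras (0.0613), S100a1 (0.127) and Ska2 (0.0734) did not pass. Without the filter Ngp (0.0711), S100a1 (0.0650) and Ska2 (0.0550) did not, and with the replicate number as a block Mras (0.0593), Zbtb8os (0.0619), Ngp (0.120), S100a1 (0.0967) and Ska2 (0.0840) did not. With quantile normalisation the adjusted p of Ska2 was 0.0532. Without mCG-PR SLAM replicate 1 the adjusted p was 0.154 for S100a1 (change -1.47), 0.114 for Ska2, 0.0579 for Zbtb8os (1.36), 0.0567 for Mid1ip1, 0.0593 for Tmem218 and 0.0548 for Eif2s3y. Without mCG-PR SLAM replicate 2 it was 0.0732 for Mras, and without WT SLAM replicate 1 it was 0.0714 for S100a1, 0.0736 for Ska2 (-1.34) and 0.0627 for Mras (1.38). Without WT SLAM replicate 2 it was 0.0700 for S100a1, 0.0738 for Zbtb8os, 0.0581 for Tspan8 and 0.0665 for Eif2s3y.

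In all, limma called 275 genes in SLAM cells, 92 higher and 183 lower (66.5% lower), of which 242 changed at least 2-fold; 1918 had an unadjusted p under 0.05. With quantile normalisation the count was 403, with 55.3% lower. The SLAM arrays spread more than the KLS arrays that set most of the error, and on simulated data 217 of 373 calls of this test were false. With array weights by sorted population, a setting chosen after the data were seen, 3 genes passed: Rras2 (adjusted p = 0.0490), Fkbp7 (0.00918) and Ogfrl1 (0.0490). With limma array weights 1 gene passed, and in a fit of the 4 SLAM arrays alone 0 passed, beside 664 at an unadjusted p under 0.05. With the replicate number as a block 69 passed, without the filter 171 and with the mean of probe sets 421. Without 1 of the SLAM arrays, its group has no spread of its own, and the error rests still more on the less variable KLS arrays. Calls kept in such a fit, in number or gene by gene, are therefore no check on robustness.

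**Figure D4:**
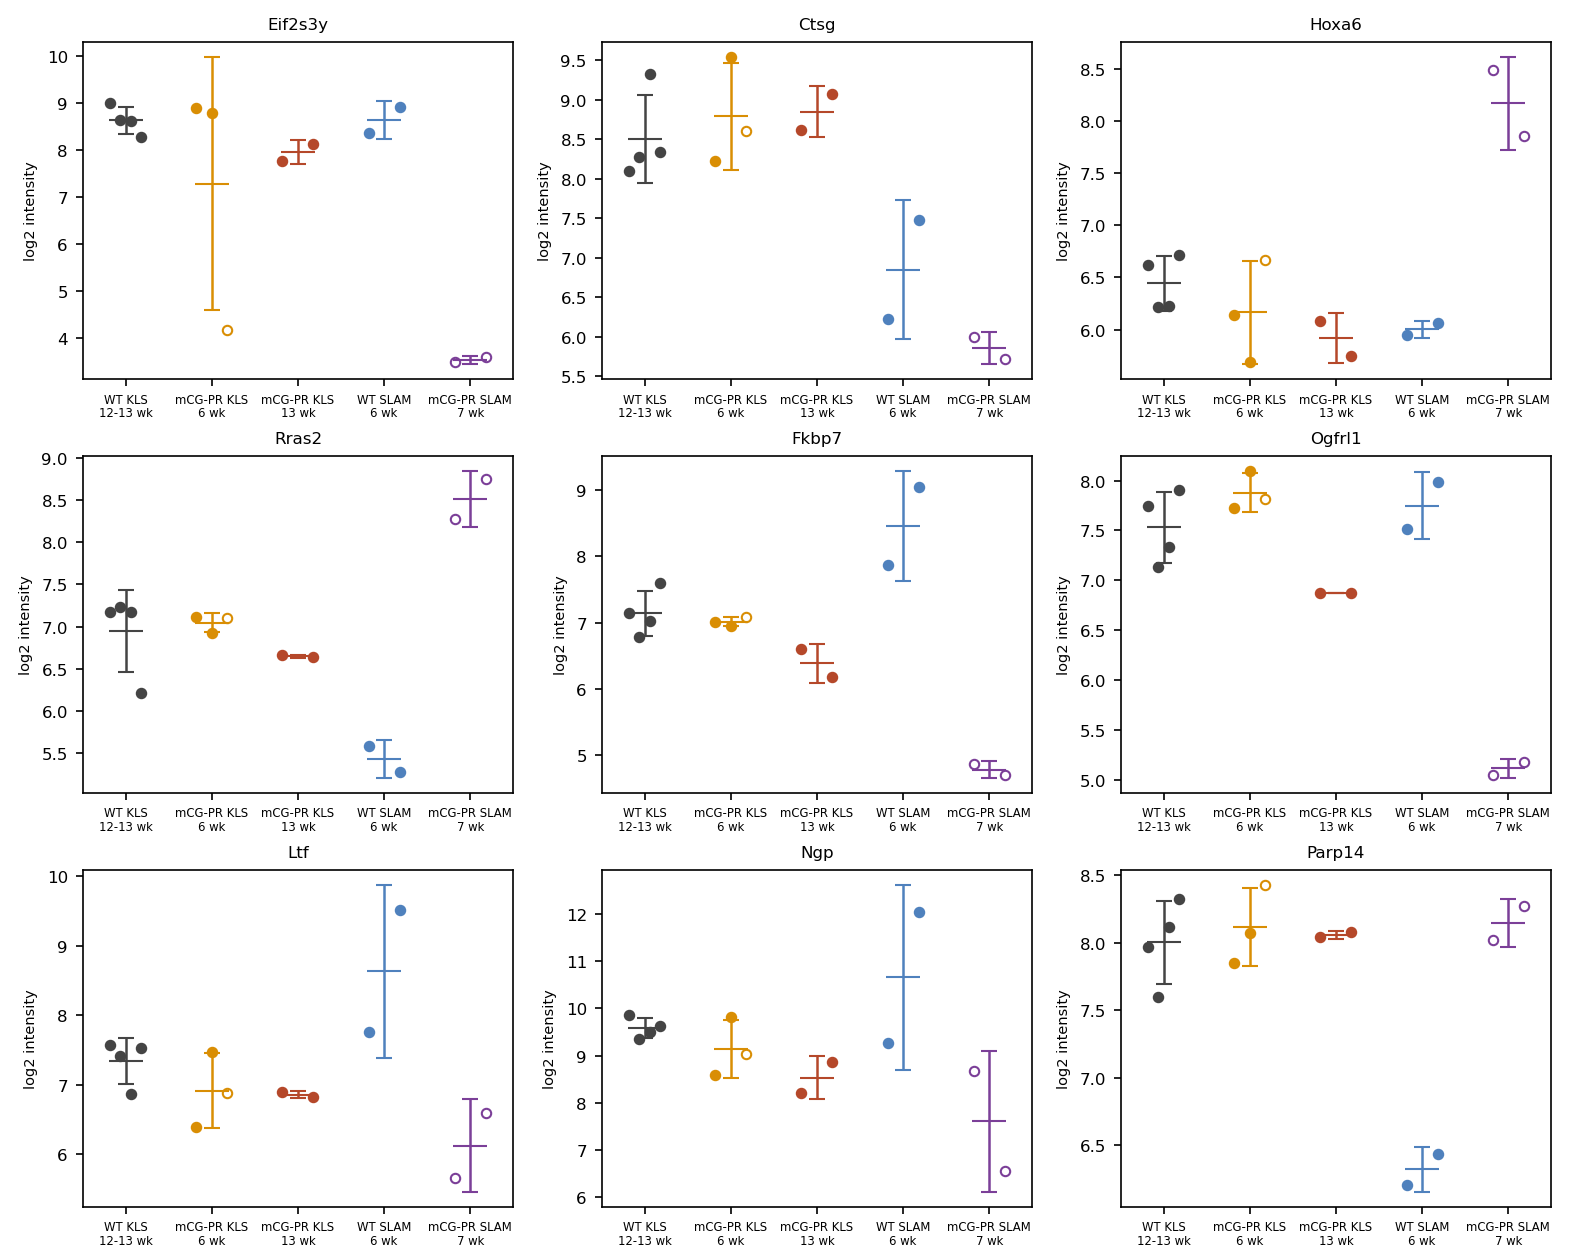
Log2 values of 9 genes by group; points are arrays, open points have low Y-linked expression, horizontal bars are group means and error bars SD. Rras2 averages 8.51 in mCG-PR SLAM and 5.43 in WT SLAM, and Fkbp7 4.79 and 8.46.

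Late neutrophil genes were lower in mCG-PR than in WT SLAM cells, with a median log2 change of -1.27 over 20 genes (camera adjusted p = 0.00172, and adjusted p = 0.600 with an estimated correlation). Of these, 2 fell over all genes and 6 adjusted over the list alone; Ltf, the iron-binding protein of neutrophil granules (-2.50 ± 0.49, adjusted p = 0.0211), and Ngp (-3.06 ± 0.75, adjusted p = 0.0498) were the 2. The neutrophil list mean was 9.41 on WT SLAM replicate 2, 7.90 on WT SLAM replicate 1, and 8.01 and 7.24 on the mCG-PR SLAM arrays. Without WT SLAM replicate 2 the median change was -0.20 (adjusted p = 0.579), and the changes of Ltf (-1.63, adjusted p = 0.0640) and Ngp (-1.67, adjusted p = 0.181) no longer passed. Without mCG-PR SLAM replicate 2 the list median was -0.55 (adjusted p = 0.192) and Ngp did not pass (-2.00, adjusted p = 0.163), and Ltf did not pass without mCG-PR SLAM replicate 1 (adjusted p = 0.0654).

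Proliferation and energy genes were also lower in mCG-PR SLAM cells. Mitotic genes had a median of -0.52 over 29 genes (adjusted p = 0.00305, and adjusted p = 0.600 with an estimated correlation), with 1 gene lower over all genes, the spindle gene Prc1 (-1.09 ± 0.26, adjusted p = 0.0413), and 4 adjusted over the list alone. DNA replication genes had a median of -0.24 over 31 genes (adjusted p = 0.0151, and adjusted p = 0.600 with an estimated correlation), with 1 lower, the thymidine kinase gene Tk1 (-1.26 ± 0.28, adjusted p = 0.0336), and 2 adjusted over the list alone. Oxidative phosphorylation genes had a median of -0.43 over 36 genes (adjusted p = 0.00932, and adjusted p = 0.600 with an estimated correlation), with 1 lower, the ATP synthase subunit gene Atp5o (-1.43 ± 0.28, adjusted p = 0.0197), and 3 adjusted over the list alone. Monocyte, macrophage and dendritic cell genes had a median of -0.48 over 22 genes (adjusted p = 0.0182, and adjusted p = 0.600 with an estimated correlation), with 0 lower over all genes and 0 adjusted over the list alone. WT SLAM replicate 2 had higher list means than replicate 1 for mitotic (by 0.77), DNA replication (0.41), oxidative phosphorylation (0.28) and monocyte and dendritic genes (0.63). Without it the adjusted p was 0.539 for mitotic (median -0.32), 0.334 for DNA replication (-0.07), 0.169 for oxidative phosphorylation and 0.548 for monocyte and dendritic genes (-0.20). Without mCG-PR SLAM replicate 1 it was 0.111 for mitotic and 0.0620 for monocyte and dendritic genes, and without replicate 2 it was 0.199 for DNA replication, 0.242 for oxidative phosphorylation (-0.23) and 0.192 for monocyte and dendritic genes. Prc1 did not pass without mCG-PR SLAM replicate 2 (adjusted p = 0.0882) or WT SLAM replicate 2 (0.0976), and without mCG-PR SLAM replicate 1 or WT SLAM replicate 2 neither Tk1 (0.0792 and 0.111) nor Atp5o (0.0518 and 0.0613) did. With quantile normalisation the oxidative phosphorylation median was -0.23 (adjusted p = 0.104), and without WT SLAM replicate 1 the mitotic median was -0.89.

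WT SLAM cells (n = 2) were then compared with WT KLS cells (n = 4) as the background difference between the populations, in which age also differed. Of 17 lymphoid-primed progenitor genes 7 fell in SLAM cells, as many adjusted over the list alone, with a list median of -0.59 (adjusted p = 1.20e-04, and adjusted p = 0.213 with an estimated correlation) that was -0.33 without WT SLAM replicate 1 and -1.05 without replicate 2. Among the 7 were Dntt, the terminal transferase of lymphoid progenitors (-5.06 ± 0.32, adjusted p = 3.35e-06, with a mean of 4.86 in SLAM cells), and Flt3 (-2.67 ± 0.18, adjusted p = 3.35e-06). The cell cycle kinase gene Cdk6 (-3.18) and the chemokine gene Ccl3 (-3.54) fell as well. The serpin gene Serpina3g rose 6.67-fold (2.74 ± 0.19, adjusted p = 3.35e-06), beside Pdgfc (1.91) and Gda (1.76). Slamf1 (1.71 ± 0.29) and Cd48 (-3.70 ± 0.27) encode receptors of the SLAM family, by which such cells are commonly sorted. In 7 of the 20 genes named by rule, Slamf1 (5.87 in KLS), Cd48 (5.13 in SLAM) and Dntt among them, the dimmer group mean lay under the filter threshold. Of 26 stem cell genes, 10 rose over all genes and 12 adjusted over the list alone, among them Pdzk1ip1 (1.32), Sult1a1 (1.65) and Vwf (1.14); the list median was 0.73 (adjusted p = 3.18e-11, and adjusted p = 0.00103 with an estimated correlation).

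Cell cycle genes were lower in WT SLAM than in WT KLS cells. All 29 mitotic genes had a negative change as deposited, 9 of them falling over all genes and 16 adjusted over the list alone, with a median of -0.85 (adjusted p = 3.06e-06, and adjusted p = 0.561 with an estimated correlation). Bub1 (-1.42), Cenpe (-1.42) and Birc5 (-1.31) were among the 9. The others, Aurkb, Cdk1, Foxm1, Kif11, Top2a and Ttk, did not pass without WT KLS replicate 3 (limma adjusted p = 0.052 to 0.112). Without WT SLAM replicate 1 the change was -0.63 instead of -1.54 for Cdk1, -0.55 instead of -1.40 for Top2a and -0.48 instead of -1.18 for Kif11. Of 31 DNA replication genes 8 fell and 11 adjusted over the list alone, including Hells (-1.96) and Gins1 (-1.61), with a median of -0.49 (adjusted p = 9.82e-04, and adjusted p = 0.561 with an estimated correlation). Stromal and endothelial genes were higher, with a median of 0.42 over 13 genes (adjusted p = 9.82e-04, and adjusted p = 0.213 with an estimated correlation), 2 of them rising over all genes (Sparc, 1.64, and Stab2, 0.63), and 4 higher and 1 lower adjusted over the list alone. Late neutrophil genes were higher by 0.42 (adjusted p = 0.00106, and adjusted p = 0.575 with an estimated correlation), with 2 rising over all genes and 2 adjusted over the list alone, Fpr2 (1.79) and Camp (1.34). Monocyte, macrophage and dendritic cell genes were higher by 0.32 (adjusted p = 0.00208, and adjusted p = 0.412 with an estimated correlation), with 2 rising over all genes and 2 adjusted over the list alone, the complement genes C1qc (1.54) and C1qb (0.86). Without WT SLAM replicate 2 the neutrophil median was -0.23 (adjusted p = 0.814) and the monocyte and dendritic median -0.01 (adjusted p = 0.227), and Fpr2 (1.45, adjusted p = 0.103), Camp (0.58, adjusted p = 0.343), Stab2 (0.46, adjusted p = 0.229) and C1qb (adjusted p = 0.0523) did not pass. Without WT SLAM replicate 1 the stromal median was 0.22 (adjusted p = 0.216), the DNA replication median -0.29 (adjusted p = 0.121), the mitotic median -0.47, the neutrophil median 1.28, the monocyte and dendritic median 0.71 and the change of Camp 2.09, and Bub1 (adjusted p = 0.0751), Cenpe (0.101), Birc5 (0.0862), Sparc (0.99, adjusted p = 0.0655) and C1qb (0.157) did not pass. Without single WT KLS arrays the adjusted p was 0.0650 to 0.0900 for Camp (replicates 1, 2 and 4), 0.0679 to 0.0988 for Stab2 (each replicate) and 0.0723 to 0.0794 for C1qb (replicates 2, 3 and 4).

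Limma called 1229 genes between WT SLAM and WT KLS cells, 254 higher and 975 lower (79.3% lower). The share depended on scaling: it was 60.4% of 1058 genes with quantile normalisation and 62.6% of 1143 with array medians subtracted. The count was 410 with the replicate number as a block, 321 with limma array weights, 330 with weights by sorted population and 439 against WT KLS replicates 3 and 4 alone. Without WT KLS replicate 1 or 3 it was 754 or 758. Of the 23 named genes 21 passed, and 17 did with weights by sorted population. Fpr2 did not pass with those weights (adjusted p = 0.0664), with limma array weights (0.0741), with the replicate number as a block (0.0591) or against WT KLS replicates 3 and 4 alone (0.134), and Gda did not with limma array weights (0.0519).

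The difference of the genotype effect between SLAM and KLS was then tested as an interaction. Low Y-linked expression coincided with genotype in the SLAM arrays, and among KLS arrays it marked only mCG-PR KLS 6 weeks replicate 3. The interaction therefore cannot separate genotype from sex. Rras2 (3.18), Hoxa6 (2.57), Gstm7 (1.99) and the immune checkpoint ligand gene Cd274 (1.86) had a more positive effect in SLAM than in KLS cells. Fkbp7 (-3.24), the tropomyosin gene Tpm4 (-3.12), Ogfrl1 (-2.48) and Siglech (-1.76, adjusted p = 0.0290, a gene outside the naming rule, taken up for its change in KLS cells) had a more negative effect in SLAM cells. All genes together shifted by a median of -0.11. Mitotic genes had a median difference of -1.02 (adjusted p = 1.11e-08, and adjusted p = 0.421 with an estimated correlation), with 1 gene passing over all genes and 14 adjusted over the list alone. The medians were -0.94 for lymphoid-primed genes (adjusted p = 0.00556, and adjusted p = 0.421 with an estimated correlation), with 1 and, adjusted over the list alone, 6 genes passing, and -0.76 for monocyte, macrophage and dendritic cell genes (adjusted p = 3.94e-04, and adjusted p = 0.396 with an estimated correlation), with 1 and, adjusted over the list alone, 3. DNA replication genes had a median of -0.53 (adjusted p = 2.42e-04, and adjusted p = 0.421 with an estimated correlation), with 1 and, adjusted over the list alone, 3 genes passing. That 1 gene, Tk1, did not pass without any 1 of the WT KLS or mCG-PR KLS 6 weeks arrays (limma adjusted p = 0.0578 to 0.0899). The 1 mitotic gene, Prc1, did not pass without WT KLS replicate 1, 2 or 4 or mCG-PR KLS 6 weeks replicate 2 or 3 (0.0580 to 0.0814). For Tk1 and Prc1, fits that leave 1 array in a group are not listed, so neither is shown to hold without the mCG-PR KLS 13 weeks or SLAM arrays. Oxidative phosphorylation genes had a median of -0.47 (adjusted p = 0.00751, and adjusted p = 0.634 with an estimated correlation), with 0 and, adjusted over the list alone, 1. Hox, Meis and Pbx genes had a median of 0.46 (adjusted p = 0.00561, and adjusted p = 0.290 with an estimated correlation), with 1 and, adjusted over the list alone, 4 higher and 1 lower. Relative to the shift of all genes these medians were -0.91 (mitotic), -0.83 (lymphoid-primed), -0.65 (monocyte and dendritic), -0.42 (DNA replication), -0.36 (oxidative phosphorylation) and 0.57 (Hox). Without mCG-PR SLAM replicate 2 the calls for lymphoid-primed (adjusted p = 0.0923), Hox (0.0808, median 0.02) and oxidative phosphorylation genes (0.212, median -0.26) were lost. Without WT SLAM replicate 2 those for lymphoid-primed (0.125, median -0.47), monocyte and dendritic (0.0581, median -0.45) and oxidative phosphorylation genes (0.0887) were lost. The Hox median was 0.17 without mCG-PR SLAM replicate 1 and 0.30 without WT SLAM replicate 1, where the DNA replication median was -0.80. Siglech did not pass without WT KLS replicate 1, 2 or 4 (adjusted p = 0.0538, 0.0608 and 0.0604) or mCG-PR KLS 13 weeks replicate 1 or 2 (0.0681 and 0.0650). The oxidative phosphorylation call was also lost with quantile normalisation (median -0.22, adjusted p = 0.0688) and against WT KLS replicates 3 and 4 alone (adjusted p = 0.0681), and Ogfrl1 did not pass with the mean of probe sets (adjusted p = 0.111).

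Limma called 90 genes for this interaction, 21 with a more positive and 69 with a more negative effect in SLAM cells (76.7% more negative), and 1600 had an unadjusted p under 0.05. That share was 57.7% of 104 genes with quantile normalisation and 64.1% of 103 with array medians subtracted. The count was 0 with limma array weights (859 at an unadjusted p under 0.05), 0 with weights by sorted population (836) and 0 against WT KLS replicates 3 and 4 alone (1132). It was 18 with the replicate number as a block, 51 without the filter and 175 with the mean of probe sets. Without single arrays it lay between 14 (without mCG-PR KLS 13 weeks replicate 1) and 538 (without WT SLAM replicate 1). Without WT SLAM replicate 2 it was 146, without mCG-PR SLAM replicate 1 or 2 it was 229 or 385, and without each of the other KLS arrays between 15 and 69.

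Ctsg, the cathepsin G gene at whose locus the transgene sits, did not differ detectably between mCG-PR and WT cells. Its mean log2 value was 8.51 ± 0.55 (SD, n = 4) in WT KLS, 8.79 ± 0.68 (SD, n = 3) in mCG-PR KLS of 6 weeks and 8.85 ± 0.32 (SD, n = 2) at 13 weeks, and the change over both ages was 0.31 ± 0.31 (limma adjusted p = 0.872). Against WT KLS replicates 3 and 4 alone that change was -0.01. In SLAM cells Ctsg was 5.86 ± 0.20 (SD, n = 2) in mCG-PR against 6.85 ± 0.88 (SD, n = 2) in WT, a change of -0.99 ± 0.48 (limma adjusted p = 0.301). That change was -1.62 without WT SLAM replicate 1 and -0.37 without replicate 2, and over its 10 probe sets it ran from -4.62 to 0.33. Ctsg was lower in WT SLAM than in WT KLS cells (-1.66 ± 0.42, adjusted p = 0.0231), a call lost without WT SLAM replicate 1 (-1.03, adjusted p = 0.180) and without WT KLS replicate 3 (adjusted p = 0.0528). It was also lost with weights by sorted population (adjusted p = 0.122), with limma array weights (0.126), with the replicate number as a block (0.0708) and against WT KLS replicates 3 and 4 alone (0.0526). The partner genes of the fusion had changes of 0.20 ± 0.19 (Pml) and 0.25 ± 0.19 (Rara) in KLS cells of both ages, and of 0.12 (Pml) and -0.07 (Rara) in SLAM cells, none of which passed.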

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

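Each test in this part, weights by sorted population aside, was set before its own result was seen, although the patterns themselves were noticed in the data. Of 168 checks of a single array lying far from the rest of its group, 7 passed, where 8.4 would be expected by chance. The distance is the gap to the nearest other array divided by the range of the group. Rara on mCG-PR KLS 6 weeks replicate 2 (log2 7.28 against a mean of 6.74 on the others) had a ratio of 0.890. Dntt on the same array (10.75 against 10.35) had a ratio of 0.718. On mCG-PR KLS 6 weeks replicate 3, the array with low Y-linked expression, the ratios were 0.761 for Eif2s3y (4.18 against 8.40), 0.743 for Cyp7b1 (6.18 against 5.67) and 0.739 for Ccl3 (9.15 against 10.31). Rras2 on WT KLS replicate 4 (6.22 against 7.19) had a ratio of 0.948, and Cdk6 on WT KLS replicate 1 (10.71 against 10.27) a ratio of 0.898.

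By the interaction test, the difference between mCG-PR and WT was not the same in SLAM and KLS cells for 90 genes. Low Y-linked expression coincided with genotype in the SLAM arrays, so sex and the transgene are not separated in it. The log2 difference was 3.18 for Rras2, 2.57 for Hoxa6, 2.10 for Dlg2, 2.07 for Eri2, 1.99 for Gstm7, 1.86 for Cd274, 1.77 for Cbx8, 1.74 for Parp14, 1.71 for Mad2l2 and 1.71 for Arsk. It was -3.24 for Fkbp7, -3.16 for Coq10b, -3.12 for Tpm4, -2.48 for Ogfrl1, -2.48 for Kif18a, -2.40 for Phospho1, -2.39 for Ankrd49, -2.38 for Dscc1, -2.38 for Ly86 and -2.37 for Med21. Ly86 did not pass without WT KLS replicate 1, 2 or 4 or any 1 of the mCG-PR KLS 6 weeks arrays (limma adjusted p = 0.0566 to 0.0937). Parp14 did not pass without WT KLS replicate 1 or 4 or mCG-PR KLS 6 weeks replicate 2 (0.0515 to 0.0604). For Ly86 and Parp14, fits that leave 1 array in a group are not listed, so neither is shown to hold without the mCG-PR KLS 13 weeks or SLAM arrays. Among gene lists, the median difference was -1.02 for mitotic, -0.94 for lymphoid-primed, -0.76 for monocyte, macrophage and dendritic cell, -0.53 for DNA replication, -0.47 for oxidative phosphorylation and 0.46 for Hox, Meis and Pbx genes. Of these 6 lists 0 passed with an estimated correlation. The count of 90 genes was 0 with limma array weights, 0 with weights by sorted population and 0 against WT KLS replicates 3 and 4 alone, and 13 of the 20 genes named had a group mean under the filter threshold.

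The first pattern is the 275 genes called between mCG-PR and WT SLAM cells. An error pooled with the less variable KLS arrays may account for part of them: the regroupings that put 1 mCG-PR and 1 WT SLAM array on each side gave 163 and 83 calls. The rule set beforehand rests on the higher count, 163, which lies between its bounds, while 83 lies below both. The regroupings therefore do not decide it. On simulated data pooled error gave 217 false among 373 calls, and weights by sorted population 28 among 122. Pooled error thus raised the false calls there. The 275 calls fell to 3 with those weights, 1 with limma array weights and 0 with the SLAM arrays alone. Weights by population also recovered fewer simulated 1-log2 changes (10% against 58%), so how many of the 275 calls pooled error accounts for stays open. The labels give no sex, and low Y-linked expression, a sign of female mice, coincided with the mCG-PR genotype here; the called genes moved by a median of -0.032 in the SLAM direction on the Y-low KLS array, against 1.31 in SLAM cells. With 1 such KLS array, sex and the transgene cannot be told apart as the source of these calls, and both stay open.

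The second pattern is the late neutrophil list, lower in mCG-PR SLAM cells by a median of -1.27. RNA of neutrophils in WT SLAM replicate 2 is a candidate source: without that array the median was -0.20, above the bound set beforehand, and without WT SLAM replicate 1 it was -1.77. The list mean of replicate 2 exceeded that of replicate 1 most for this list (by 1.52). It was also higher for primary granule (0.89), mitotic (0.77), lymphoid-primed (0.66), B cell (0.65) and erythroid genes (0.58), among others. The difference was lower for stromal (-0.59), stem cell (-0.10), p53 target (-0.07) and Notch and Wnt genes (-0.02). It was thus not confined to neutrophil genes, and RNA of other cells was not tested. S100a8, S100a9 and Ngp had log2 values of 12.91, 12.69 and 12.05 on WT SLAM replicate 2, against 11.79, 11.72 and 9.27 on replicate 1, and 17 of 20 members were highest on replicate 2 among the SLAM arrays. A lineage-negative gate would remove neutrophils, but the gating is not given in the sources used here. The 20 members had passed a filter on the mean of all 13 arrays. That they also lay above it in KLS cells was therefore nearly fixed in advance. Their KLS means ran from 6.04 (Mmp9) to 11.55 (S100a9). Neither point decides whether neutrophil RNA was present. A biological difference between the WT SLAM mice was not tested and stays open.

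The third pattern is the lower stem cell list and the higher lymphoid-primed and mitotic lists in mCG-PR KLS cells. Sex, as read from Y-linked expression, is argued against, since without the Y-low array each list kept its direction, with a smallest ratio of medians of 0.889. WT KLS replicates 1 and 2 carry label numbers apart from the other 11 arrays and are those of 13 weeks; against replicates 3 and 4 alone the smallest ratio was 0.500, at the bound set beforehand, so a handling or age difference stays open. A KLS mix with fewer SLAM-like cells could also give this pattern: a score of SLAM-like expression differed by -0.26 in mCG-PR KLS arrays from WT, with an exact permutation p of 0.0556 over 126 splits, which leaves it open. Late neutrophil genes, high on WT SLAM replicate 2, were not kept out of the score, so it may mix neutrophil signal with stem cell content. The mCG-PR mice of 6 weeks were also younger than every WT KLS mouse, and age stays open for them. At 13 weeks (n = 2), against the same WT arrays, the medians were -0.12 for stem cell, 0.34 for lymphoid-primed and 0.51 for mitotic genes. An effect of the transgene within KLS cells stays open as well.

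Chance cannot be excluded for the single gene called in KLS of 6 weeks: 3 of the 35 splits of the 7 arrays gave as many calls, with 1 for the real split and 1 as the highest of the others. For both ages of KLS the real split gave 0 calls and the highest of the others 0, and since every split gives at least 0 calls, this count decides nothing. Counted by lists, 8 of the 35 splits of the KLS arrays of 6 weeks and WT gave as many passing lists as the real split, with 8 for the real split and 11 as the highest of the others. For both ages 5 of 100 splits gave as many, with 11 for the real split and 11 as the highest of the others. Chance therefore cannot be excluded for either number of lists.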

How the results depend on the processing

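Weights by sorted population, the covariate for low Y-linked expression and the permutation of list means were chosen only after the data were seen. The Y-linked covariate gave the same fit as leaving out mCG-PR KLS 6 weeks replicate 3, so it is not a separate check. The cause of the changes below was not tested unless the setting itself removes arrays. Among named genes, 1067 results under the alternatives kept their direction and side of the threshold, 176 no longer passed, 41 newly passed and 9 reversed; leaving out single arrays gave 740, 117, 7 and 16. Among list medians, 242 were kept and 87 lost, and 294 and 43 when single arrays were left out. Arrays give no depth, and dim signal near background limits genes close to the filter. Counts of genes for KLS 13 weeks were 12 with the compared groups alone and 12 with array weights. For KLS 6 weeks (1 gene) they were 0 with the mean of probe sets, 0 with the replicate number as a block, 0 against WT KLS replicates 3 and 4 alone, 0 with the Y-linked covariate, 2 with the compared groups alone, 4 with array weights and 12 with population weights. For both ages (0) they were 2 without the filter, 1 with the mean of probe sets, 9 with the compared groups alone, 29 with array weights and 12 with population weights. For SLAM (275) they were 171 without the filter, 421 with the mean of probe sets, 69 with the block, 0 with the compared groups alone, 1 with array weights and 3 with population weights. For 13 against 6 weeks they were 1 with array weights and 1 with population weights. For WT SLAM against WT KLS (1229) they were 618 at 2-fold or more, 410 with the block, 321 with array weights, 439 against WT KLS replicates 3 and 4 alone and 330 with population weights. For the interaction (90) they were 51 without the filter, 175 with the mean of probe sets, 18 with the block, 0 with array weights, 0 against WT KLS replicates 3 and 4 alone and 0 with population weights. Pairing was checked by the correlation of residuals: 21 pairs of arrays with the same replicate number gave -0.066 to 0.077 and 45 other pairs -0.078 to 0.090, so the numbers showed no pairing.

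Counts of lists passing with an estimated correlation were 0 (KLS 13 weeks), 1 (KLS 6 weeks), 1 (both ages), 0 (SLAM), 1 (WT SLAM against WT KLS) and 0 (interaction), against 7, 8, 11, 5, 7 and 6. With fry they were 1 for KLS 13 weeks, 5 for KLS 6 weeks, 4 for both ages and 0 for SLAM. Without the filter they were 5 for KLS 13 weeks, 6 for both ages, 9 for SLAM and 10 for the interaction. Against WT KLS replicates 3 and 4 alone, 5 of the 7 lists of KLS 13 weeks, 7 of the 8 of KLS 6 weeks, 7 of the 11 of both ages and 5 of the 6 of the interaction were shared with those called above, and with quantile normalisation 5 of the 6 of the interaction and 4 of the 5 of SLAM were. With the Y-linked covariate 13 passed for KLS 6 weeks, with the block 1 passed for 13 against 6 weeks, and permutation of list means with array medians subtracted gave 0 for both ages. Leaving out single arrays gave gene counts of 0 to 0 (KLS 13 weeks), 0 to 3 (KLS 6 weeks), 0 to 6 (both ages), 371 to 825 (SLAM), 0 to 0 (13 against 6 weeks), 754 to 1360 (WT SLAM against WT KLS) and 14 to 538 (interaction). List counts ranged from 6 to 9, 6 to 13, 8 to 14, 1 to 9, 0 to 1, 7 to 9 and 3 to 9 in the same order; an array left alone in its group was assumed to vary like the other groups. Of lists that passed, 4 medians changed sign without a single array, each with its call lost: WT SLAM against WT KLS without WT SLAM replicate 2, late neutrophil from 0.42 to -0.23 and monocyte and dendritic from 0.32 to -0.01; both ages of KLS, Hox from -0.07 to 0.02 without WT KLS replicate 1 and erythroid from -0.08 to 0.06 without WT KLS replicate 3. Among named genes, values that reversed belonged to genes that did not pass. Pml in KLS 13 weeks was -0.059 with quantile normalisation, -0.020 with array medians subtracted and -0.105 to 0.139 without single arrays. Pml in SLAM was -0.265 to 0.505 without single arrays, and its interaction was 0.078 with quantile normalisation, 0.045 with medians subtracted and -0.432 to 0.337 without single arrays. Ctsg against WT KLS replicates 3 and 4 alone was -0.036 in KLS 6 weeks and -0.014 over both ages; it was -0.089 to 0.568 in KLS 6 weeks without single arrays. Ctsg for 13 against 6 weeks was -0.038 with the Y-linked covariate and -0.227 to 0.430 without single arrays. Rara in WT SLAM against WT KLS was 0.084 with the mean of probe sets, 0.027 with medians subtracted and -0.435 to 0.261 without single arrays; Rara without single arrays was -0.414 to 0.282 in SLAM and -0.648 to 0.048 in the interaction.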

Other observations

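Of the tests in this part, the weights by sorted population were chosen only after the data were seen. Primary granule genes, the products of promyelocytes, did not pass as a list in any comparison, although 5 of 18 were lower in WT SLAM than in WT KLS cells, as many adjusted over the list alone. Among the 5 were Serpinb1a (-2.30 ± 0.29, adjusted p = 5.62e-04), Nkg7 (-2.20 ± 0.32, adjusted p = 0.00134), Plac8 (-1.96 ± 0.47, adjusted p = 0.0190) and Mpo (-2.02, adjusted p = 0.0385). Without WT SLAM replicate 1 the change was -0.69 for Plac8 and -0.63 for Mpo, and without replicate 2 it was -3.22 and -3.42. Mpo did not pass when any 1 of the WT KLS arrays was left out (limma adjusted p = 0.0582 to 0.0922). The list median was 0.08 in mCG-PR KLS of both ages (adjusted p = 0.611) and -0.30 in mCG-PR SLAM (adjusted p = 0.143). Retinoic acid pathway genes had a median of 0.14 in mCG-PR KLS of both ages (adjusted p = 0.934) and 0.00020 in mCG-PR SLAM (adjusted p = 0.868); between the WT populations Tgm2, a transglutaminase induced by retinoic acid, was 2.82-fold higher in SLAM (adjusted p = 6.07e-04) and Dhrs3, a retinaldehyde reductase, lower (-0.84 ± 0.20, adjusted p = 0.0202, and 0.0970 without WT SLAM replicate 1). In mCG-PR SLAM cells the stem cell genes Pdzk1ip1 (-1.08 ± 0.19, adjusted p = 0.0120) and Tek (-1.21 ± 0.27, adjusted p = 0.0336), the matrix gene Sparc (-1.68 ± 0.38, adjusted p = 0.0380), the Notch modifier Lfng (-1.21 ± 0.23, adjusted p = 0.0178) and the p53 target Plk2 (-1.55 ± 0.33, adjusted p = 0.0293) were lower, and Flt3 was higher (0.87 ± 0.21, adjusted p = 0.0445). The stem cell list itself had a median of 0.0082 in SLAM cells (13 genes positive and 13 negative, adjusted p = 0.691), and the lymphoid-primed list, to which Flt3 belongs, one of -0.39 (adjusted p = 0.143), opposite to Flt3. Flt3 did not pass without mCG-PR SLAM replicate 1 or 2 or WT SLAM replicate 2 (adjusted p = 0.0542, 0.0847 and 0.111), nor Tek without mCG-PR SLAM replicate 1 (0.107) or WT SLAM replicate 1 (0.0681). Sparc did not pass without mCG-PR SLAM replicate 1 or 2 (0.0634 and 0.0631) or WT SLAM replicate 1 (-1.03, adjusted p = 0.103), nor Plk2 without mCG-PR SLAM replicate 2 (0.0620) or WT SLAM replicate 2 (0.0937). These 6 SLAM calls are among the 275 of the pooled error, and none of them is among the 3 that passed with weights by sorted population.

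The other lists that camera did not call in mCG-PR KLS of both ages had medians of 0.32 for mast cell and basophil (adjusted p = 0.0668), 0.25 for B cell (0.185), 0.23 for quiescence (0.452), 0.14 for interferon response (0.452), 0.09 for p53 target (0.461), 0.05 for immediate early (0.960), -0.02 for megakaryocyte (0.117), 0.07 for stromal and endothelial (0.611) and 0.11 for oxidative phosphorylation genes (0.810). Of these, the mast cell, stromal and interferon lists passed the exact permutation of list means (adjusted p = 0.0349, 0.0349 and 0.0437), a test chosen after the data were seen, and 0 lists did with array medians subtracted. In mCG-PR SLAM the medians of the same lists, oxidative phosphorylation aside, were -0.01 (adjusted p = 0.859), -0.34 (0.148), 0.15 (0.868), 0.12 (0.143), -0.14 (0.143), -0.32 (0.0916), -0.41 (0.143) and -0.20 (0.172). The mast cell list was led by Mcpt8 (1.60 ± 0.52) and Cpa3 (1.21 ± 0.49) in KLS cells of both ages, neither of which passed.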
